A study of Mus musculus with 6 samples.

How the data were processed

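Bulk RNA-seq was performed on mouse placenta from 3 wildtype animals (Emp2+/+) and from 3 animals labelled Emp2 knockout (Emp2-/-). EMP2, epithelial membrane protein 2, is a tetraspan membrane protein. Per the labels' protocols, snap-frozen tissue gave total RNA with a column kit, and paired-end stranded libraries were made with the KAPA Stranded RNA-Seq Kit. The labels describe 3 biological replicates per genotype and give no litter, batch or day. They give the stage in conflicting ways, as embryonic day 16.5 in the age label and as day 13.5 in the growth protocol. All samples are labelled female.

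The authors deposited a table of 38293 genes with 1 value per gene and library, whose unit is taken here as RPKM, reads scaled by gene length and by library total. Neither the header nor the labels name the unit. It was inferred from the values, which were not whole, and whose smallest steps varied as the inverse of exon length. Per the submitters' processing notes, STAR, HTSeq and the mouse build GRCm38 were used; their versions, the annotation, the strand setting of the counting and the length behind each value are not given in the sources used here. Columns were matched to samples by the genotype code and number in their names, with "mt" read as mutant, and 0 value columns were left unused.

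Whole reads were solved from the RPKM steps, with each library's total and each gene's length as unknowns. The common scale of the totals was set from the GENCODE M21 exon lengths of protein-coding genes with low values. At a tolerance of 0.03 reads, 22710 of the 22711 genes above 0 in any library came out as whole reads. The solved totals were 29130008, 29076143 and 31429034 reads for wildtype replicates 1 to 3, and 27365233, 28132914 and 28600532 for knockout replicates 1 to 3. On simulated data with 1000 genes, the exact reads came back for 99.0% and the reads up to a common factor for 99.9%. These genes were drawn from those already solved, and the library totals were taken as known, so recovery of the totals was not tested. The solution is the fewest reads that fit, so a gene's reads may be a multiple of those given. The solved length was 0.925 of the GENCODE M21 exon length in the median protein-coding gene. Since such exon lengths had set the scale, this ratio is not an independent check. For 332 genes with a mean RPKM of 1 or more the solved length was 20 bases or less, among them 245 lincRNAs. The RPKM of these 332 genes therefore does not compare with that of other genes. Of 2112 lincRNAs listed, 251 were above 0, and of 1603 snoRNAs, 0 were. H19 and Malat1 were listed at 0 in every library.

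The comparison had been planned on read counts. Since the deposited values were RPKM, the fallback fixed in the same plan became the main test. Values were taken as log2(RPKM + 1), genes with a mean RPKM of 1 or more over the 6 libraries were kept (12963), and limma 3.58.1 in R 4.3.3 was fitted with genotype as the only term and with an intensity trend in the variance (limma-trend). The Benjamini-Hochberg adjusted p threshold was 0.05. Fold changes are on the log2(RPKM + 1) scale, which understates the change of low genes. Emp2 and other named genes were placed with GENCODE M21 on GRCm38. Read depth limits the precision of low genes, and counting error is only part of the spread between placentas.

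Before the data were examined, 27 gene lists were fixed: pathways, placental and maternal cell types, signs of library make-up and genes near Emp2. Lists with 5 or more measured members (26) were tested with limma's camera, two-sided, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Some genes stand in several lists. The rule for named genes was also fixed then. It took Emp2, and the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold with a mean of 2 CPM (reads per 1e6 library reads) or more and no overlap of the groups, with predicted genes passed over. From each list it took up to 3 members past the threshold, or, where none passed, the member with the smallest p. Where fewer than 10 genes passed, it took the 10 genes with the smallest p. Other list members are named in the order of their p, and were chosen after their values were seen. Genes within 5 Mb of Emp2 were compared with the rest by Fisher's exact test.

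The fit was tested on simulated reads drawn from the libraries' means and spread, with 200 of 12963 genes changed, for 3 against 3 libraries. It recovered 12.0% of 50 genes changed 1.5-fold, 42.0% of 50 changed 2-fold, 76.0% of 50 changed 3-fold and 90.0% of 50 changed 4-fold. It made 7 false calls among 117. In a simulation with the endothelium list raised 1.5-fold, camera called that list and 0 others. Genes were drawn independently there, whereas the estimated correlation within that list was 0.30 in the real libraries. The simulation therefore does not show how often camera with a preset correlation calls lists falsely in these data.

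The alternatives fixed before the data were examined were a pseudocount of 0.1, no filter, a filter at a mean of 1 CPM, median-ratio scaling, depth without haemoglobin and prolactin genes, limma-voom on the solved reads, a replicate block, each library left out in turn, and for the lists an estimated correlation, ranks, fry and the removal of multigene families. Chosen after seeing the data were a filter at a mean of 10 reads, removal of genes solved to 20 bases or less, a term for Y-linked RNA, use of the libraries with Y-linked RNA only, removal of a spline trend (4 degrees of freedom each) on gene length and GC content from each library, that removal with wildtype replicate 3 left out, quantile normalization and robust variance estimates. Gene length and GC content were available for 99.3% of the protein-coding genes tested.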

Results

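RNA was measured in 6 mouse placentas, 3 wildtype and 3 labelled Emp2 knockout, to ask how loss of EMP2, a tetraspan protein of epithelial membranes, alters the placenta and its blood vessel growth. The libraries held between 27365233 and 31429034 reads, as solved from the deposited RPKM values. Between 97.8% and 98.4% of each total lay in the genes listed.

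Emp2 itself was measured first. The gene (ENSMUSG00000022505) lies on the minus strand of chromosome 16, from 10281749 to 10313968 (GRCm38). Emp2 stood at 8.79, 9.18 and 8.19 RPKM in wildtype replicates 1 to 3. In the libraries labelled knockout it stood at 5.998, 8.70 and 7.70 RPKM, from 540, 805 and 725 reads. The means were 8.72 ± 0.497 RPKM (SD, n = 3) and 7.47 ± 1.37 RPKM (SD, n = 3). The log2 fold change was -0.21 (95% interval -0.54 to 0.12; limma-trend adjusted p = 0.425), and the groups overlapped. A value for the whole gene does not show whether part of the transcript was missing. Because Emp2 RNA was not clearly lower, the knockout group is named by its label throughout, and each direction below rests on that label.

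Sex-linked RNA also set the libraries apart. Ddx3y, a Y-linked RNA helicase, had 1001, 1011 and 1571 reads in the wildtype libraries and 1228 in knockout replicate 1, against 3 and 27 reads in knockout replicates 2 and 3. Eif2s3y, Kdm5d and Uty together with Ddx3y gave 1983, 2769, 3630 and 2890 reads in the former 4 libraries and 5 and 69 in the latter pair. Xist, the RNA that coats the inactive X chromosome, had 1155, 2011, 3727 and 1524 reads against 25963 and 26210. All 6 placentas are labelled female, but the Y-linked reads of the former 4 libraries go against that label for them. Placentas with little Y-linked RNA were found only among those labelled knockout, so sex and genotype were partly confounded.

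**Figure D1:**
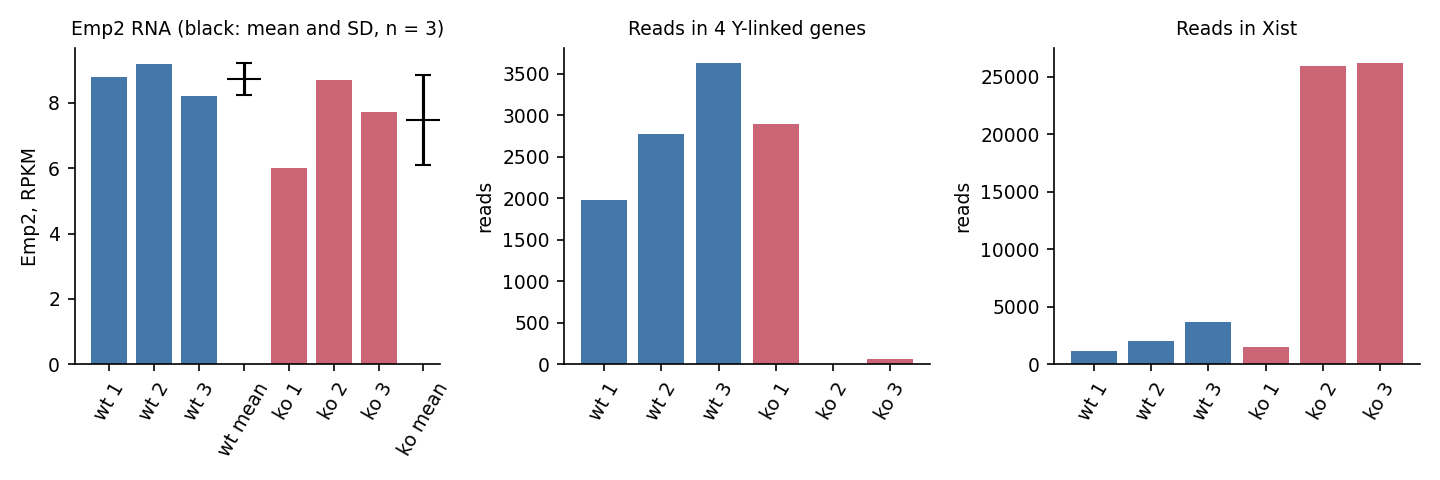
Emp2 in RPKM with the mean and SD of each group (left), reads summed over 4 Y-linked genes (middle) and reads in Xist (right), by library, with wildtype (wt) in blue and libraries labelled Emp2 knockout (ko) in red. Emp2 ranged from 5.998 to 8.70 RPKM in the knockout libraries and from 8.19 to 9.18 in wildtype, and ko 2 and ko 3 had 5 and 69 Y-linked reads.

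Genotype was then compared gene by gene. Of 12963 genes tested, 2 passed the adjusted p threshold in limma-trend, 1 higher and 1 lower in the libraries labelled knockout. Both met the 2-fold limit on the log2(RPKM + 1) scale, from values of 2 reads or fewer. Gm13684, a lincRNA, had 0 reads in each wildtype library and 1, 2 and 1 reads in the knockout libraries (adjusted p = 0.00474). Gm12112, a pseudogene, had 2, 2 and 1 reads in wildtype and 0 in the knockout libraries (adjusted p = 0.00474). Both were solved to a length of 2 bases, which inflates their RPKM, and no fold is given at this depth. With genes under a mean of 10 reads left out, 0 genes passed in limma-trend, and limma-voom on the solved reads called 0. At an unadjusted p under 0.05 there were 2160 genes by limma-trend with all libraries, 1160 higher and 1000 lower, and 2262 by limma-voom. The balance of directions turned with the scaling, to 1032 higher and 1303 lower under median-ratio scaling and 1088 and 1145 with depth taken without haemoglobin and prolactin genes. The groups did not overlap for 21.7% of the genes, where chance gives 10% on average over the ways to split the libraries. Genes move together across libraries, so a single split can lie far from that average. Other splits into 3 and 3 gave from 66 to 2244 genes at an unadjusted p under 0.05 in limma-trend. The share of 21.7% therefore does not by itself show a genotype effect.

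Of the 10 genes with the smallest p, 3 were protein-coding, and none of these passed the threshold. Lyve1, a hyaluronan receptor of lymphatic and some other endothelium and of some macrophages, lies on chromosome 7. It stood at 14.0 ± 0.497 RPKM (SD, n = 3) in the libraries labelled knockout and 7.51 ± 0.765 (SD, n = 3) in wildtype, a log2 fold change of 0.82 (95% interval 0.57 to 1.06; limma-trend adjusted p = 0.222). Lst1, a leukocyte transcript, stood at 3.88 ± 0.238 RPKM against 6.69 ± 0.223 (log2 fold change -0.66; adjusted p = 0.281). Cox7a1, a subunit of cytochrome c oxidase, stood at 12.2 ± 1.61 RPKM against 24.0 ± 2.88 (log2 fold change -0.92; adjusted p = 0.281). The rest were the 2 genes above and 5 low-read lincRNAs or pseudogenes: AC108833.1, Gm12411, Rpl31-ps9, AC164548.1 and Gm11425. Each of these 5 was lower in the libraries labelled knockout and had a limma-trend adjusted p between 0.0693 and 0.281.

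Wildtype replicate 3 lay apart from the other wildtype libraries. The first principal component (42.6% of the variance) placed wildtype replicates 1 and 2 at -32.0 and -30.4, wildtype replicate 3 at 11.95, and the knockout libraries at 9.99, 27.3 and 13.05. The second (20.9%) set wildtype replicate 3 apart from both groups, at -31.7 against 8.39 and -1.62 in the other wildtype libraries and 5.79, 20.3 and -1.15 in the knockout libraries. Its Pearson correlations with wildtype replicates 1 and 2, across genes, were 0.958 and 0.962, and with the knockout libraries 0.972, 0.961 and 0.973. Without wildtype replicate 3, limma-trend called 3374 genes, 2148 higher and 1226 lower; leaving out the wildtype library nearest the knockout group on the first component, and farthest from its own, favours more calls by construction. With a trend on gene length and GC content also removed, 980 genes passed, 228 higher and 752 lower.

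**Figure D2:**
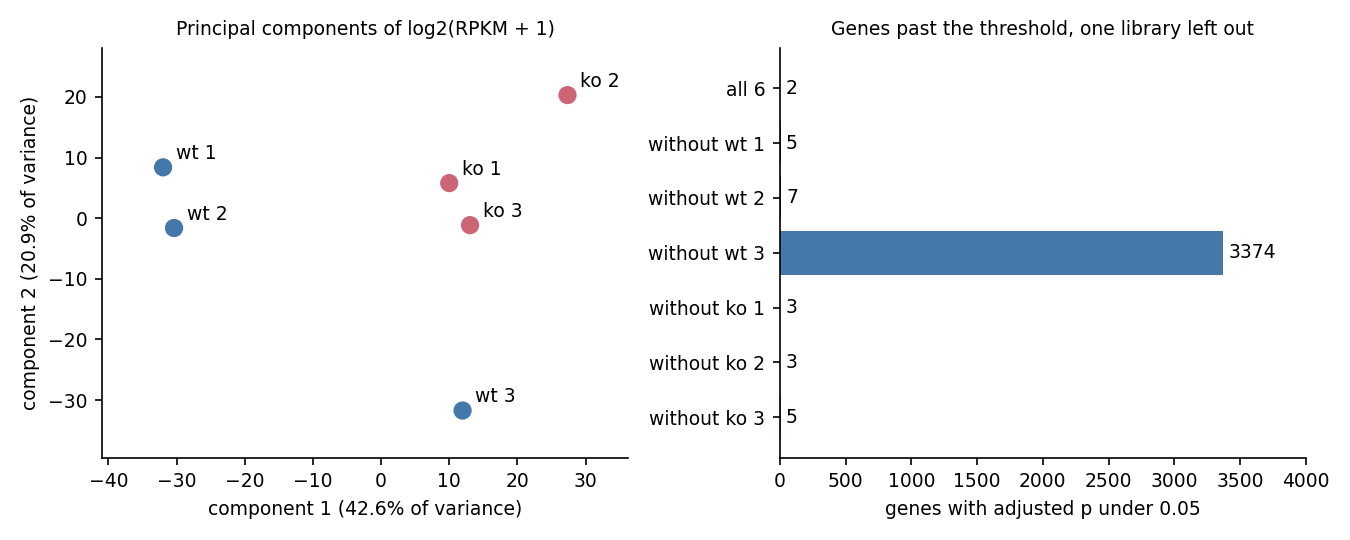
Left, principal components 1 and 2 of log2(RPKM + 1) for the 6 libraries (wt, wildtype; ko, labelled Emp2 knockout). Right, the number of genes with an adjusted p under 0.05 in limma-trend with all libraries (2) and with each library left out, which was 3374 without wt 3 and between 3 and 7 otherwise.

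Gene lists fixed before the data were examined were compared next. Camera with a preset correlation called 16 of 26 lists, 11 higher and 5 lower in the libraries labelled knockout. None was called with an estimated correlation, where the smallest adjusted p was 0.546, nor by fry for a shift in one direction, where it was 0.166. Fry's test for change in either direction, which does not compare a list with other genes, called the macrophage list (adjusted p = 8.94e-05) and the endothelial list (0.0406). No member of any list passed the threshold over all genes tested.

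Blood vessel lists were called higher in the libraries labelled knockout by camera with a preset correlation, on values and on ranks. They were not called with an estimated correlation or by fry for a shift in one direction. Of 31 measured angiogenesis genes, 28 had higher means and 3 lower, with a median log2 fold change of 0.37 (camera adjusted p = 2.16e-06; adjusted p = 0.546 with an estimated correlation). Adjusted over the list alone, 5 passed, all higher. Eng, a coreceptor for TGF-beta in endothelium, stood at 24.9 ± 2.72 RPKM against 16.9 ± 0.924 in wildtype (SD, n = 3 each; list-alone limma-trend adjusted p = 0.0321). Kdr, the main VEGF receptor, stood at 16.4 ± 1.76 against 9.69 ± 1.84 RPKM, and Tek, the angiopoietin receptor, at 8.91 ± 1.97 against 5.29 ± 0.239 RPKM. Of 28 endothelial markers, 24 had higher means, with a median of 0.39 (camera adjusted p = 1.17e-05; adjusted p = 0.546 with an estimated correlation), and 11 passed adjusted over the list alone, all higher, led by Lyve1. The per-library medians of the endothelial list against the wildtype mean were 0.39, 0.61 and 0.18 in knockout replicates 1 to 3 and between -0.04 and 0.06 in wildtype. With 1 library left out, the median of this list ranged from 0.25 to 0.52.

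Matrix, smooth muscle and EMP2-partner lists went the same way. Of 40 fibroblast and matrix genes, 39 had higher means, with a median of 0.64 (camera adjusted p = 8.63e-08; adjusted p = 0.546 with an estimated correlation). Timp3, an inhibitor of metalloproteinases, stood at 49.5 ± 1.54 RPKM against 31.8 ± 2.96 and was the list's only member past the threshold adjusted over the list alone. The list's median was 0.44, 0.99 and 0.26 in knockout replicates 1 to 3, and ranged from 0.36 to 0.78 with 1 library left out. The basement membrane collagens Col4a1 and Col4a2 stood at 482 ± 99.1 against 287 ± 51.2 RPKM and at 289 ± 63.0 against 166 ± 32.5 RPKM. Of 25 genes of the EMP family and the integrins and caveolins EMP2 acts with, 23 had higher means, with a median of 0.36 (camera adjusted p = 1.71e-05; adjusted p = 0.546 with an estimated correlation). Itga2, an integrin subunit that binds collagen, stood at 6.20 ± 0.525 against 4.39 ± 0.153 RPKM; 0 of the 25 passed adjusted over the list alone. Of 12 smooth muscle genes, 11 had higher means, with a median of 0.44 (camera adjusted p = 0.0328; adjusted p = 0.598 with an estimated correlation). Mylk, myosin light chain kinase, stood at 10.6 ± 3.26 against 6.58 ± 1.07 RPKM. That list's median was 0.95 in knockout replicate 2 and 0.18 and 0.12 in knockout replicates 1 and 3, and its call ended without knockout replicate 2 (median 0.14, camera adjusted p = 0.176) or without wildtype replicate 3 (median 0.28, 0.396). It also ended with a term for Y-linked RNA (0.328) and in the libraries with Y-linked RNA only (0.180), both with the median of knockout replicate 1, 0.18.

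Trophoblast lists moved in both directions. Of 23 syncytiotrophoblast genes, which mark the exchange layer of the labyrinth, 19 had higher means, with a median of 0.40 (camera adjusted p = 0.000686; adjusted p = 0.598 with an estimated correlation). Synb, the fusogen syncytin B, stood at 68.0 ± 2.48 against 41.4 ± 8.91 RPKM, and Gcm1, a transcription factor of syncytiotrophoblast, at 15.8 ± 1.39 against 10.5 ± 2.16 RPKM. Of 32 nutrient transporters, 28 had higher means, with a median of 0.19 (camera adjusted p = 0.00115; adjusted p = 0.546 with an estimated correlation). Slc7a8, an amino acid transporter, stood at 72.8 ± 5.005 against 50.3 ± 4.68 RPKM. The transporter list's median overlapped between the groups, at -0.08, -0.08 and 0.16 in wildtype replicates 1 to 3 and 0.13, 0.22 and 0.26 in the knockout libraries. Of 33 imprinted genes, 32 had higher means, with a median of 0.33 (camera adjusted p = 2.37e-05; adjusted p = 0.546 with an estimated correlation). Slc22a3, an organic cation transporter, stood at 24.4 ± 2.22 against 16.6 ± 1.96 RPKM. None of the members of these 3 lists passed adjusted over the list alone.

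Junctional zone lists were called lower by camera with a preset correlation, and these calls depended on the setting. Of 21 giant cell genes, 17 had lower means, with a median of -0.44 (camera adjusted p = 4.66e-05; adjusted p = 0.546 with an estimated correlation). Prl7a1, a placental prolactin-family hormone, stood at 64.0 ± 21.9 RPKM against 154.5 ± 35.1. Of 36 spongiotrophoblast and glycogen cell genes, 25 had lower means, with a median of -0.23 (camera adjusted p = 0.00865; adjusted p = 0.598 with an estimated correlation). Prl6a1, another gene of that family, stood at 3.41 ± 0.188 against 7.42 ± 2.27 RPKM. With multigene families left out, whose copies can share reads, the spongiotrophoblast list's median was 0.09 and the call ended (camera adjusted p = 0.876), and the giant cell call ended with a median of -0.35 (0.0618). Quantile normalization also ended the giant cell call (median -0.11, camera adjusted p = 0.110), and so did a term for Y-linked RNA, which leaves knockout replicate 1 alone against wildtype (median -0.29, 0.116), and the libraries with Y-linked RNA only (0.0913). The spongiotrophoblast call ended in those settings too (median -0.05, 0.865 and 0.814). The spongiotrophoblast median against the wildtype mean was 0.17, 0.23 and -0.35 in wildtype replicates 1 to 3 and -0.05, -0.63 and -0.05 in the knockout libraries; the call ended without wildtype replicate 1, wildtype replicate 2 or knockout replicate 2 (camera adjusted p = 0.133, 0.0714 and 0.288), and with no filter on low values, where the median stayed at -0.23 (0.0678). None of the members of either list passed adjusted over the list alone.

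Yolk sac endoderm genes split the knockout libraries. Of 22 genes, 19 had higher means, with a median of 0.55 (camera adjusted p = 0.00233; adjusted p = 0.668 with an estimated correlation), and 0 passed adjusted over the list alone. The list's median was -0.30 in knockout replicate 1, which had Y-linked RNA, and 0.94 and 0.93 in knockout replicates 2 and 3. Cubn, an endocytic receptor of absorptive epithelia, stood at 20.3, 67.9 and 23.7 RPKM in the knockout libraries and at 10.6 ± 2.47 in wildtype. The call ended without wildtype replicate 3 (median 0.58, camera adjusted p = 0.327) or without knockout replicate 3 (median 0.41, 0.0629), so the median stayed as large in the former. With a term for Y-linked RNA, which compares knockout replicate 1 alone with wildtype and so restates that library's value, camera with a preset correlation called the list lower (median -0.30, adjusted p = 0.000386), as it did in the libraries with Y-linked RNA only (0.00270).

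Coagulation and immediate early genes were called higher. Of 33 coagulation and fibrinolysis genes, 28 had higher means, with a median of 0.22 (camera adjusted p = 0.0107; adjusted p = 0.546 with an estimated correlation), and F2rl1, a protease-activated receptor, stood at 24.2 ± 1.44 against 16.8 ± 2.18 RPKM. Of 22 immediate early and heat shock genes, which move with tissue handling, 19 had higher means, with a median of 0.19 (camera adjusted p = 0.00332; adjusted p = 0.546 with an estimated correlation), and Nr4a1, an early response receptor, stood at 5.52 ± 0.476 against 3.94 ± 0.241 RPKM. Neither list had a member past the threshold adjusted over the list alone. Without wildtype replicate 3, both calls ended (camera adjusted p = 0.327 and 0.155), though the medians, 0.31 and 0.20, did not shrink. The coagulation call also ended with a term for Y-linked RNA (camera adjusted p = 0.636) and in the libraries with Y-linked RNA only (0.535), where the median, that of knockout replicate 1 alone, shrank to 0.05.

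Signs of library make-up moved with the groups too. All 40 ribosomal protein genes had lower means in the libraries labelled knockout, with a median of -0.56 (camera adjusted p = 1.80e-20; adjusted p = 0.546 with an estimated correlation), and 26 passed adjusted over the list alone. Rpl5 stood at 3.42 ± 0.278 RPKM against 5.44 ± 0.465, and Rps24 at 334 ± 38.7 against 817 ± 262 RPKM. Ribosomal protein genes have many near-identical pseudogenes, so their levels are uncertain. The list's median was -0.43 in wildtype replicate 3 and between -0.61 and -0.51 in the knockout libraries. Of 11 replication-dependent histone genes, 10 had lower means, with a median of -0.39 (camera adjusted p = 2.07e-05; adjusted p = 0.546 with an estimated correlation), Hist1h2bj at 2.21 ± 0.924 against 5.04 ± 1.33 RPKM, and 0 passed adjusted over the list alone. All 8 mitochondrially encoded genes had lower means, with a median of -0.54 (camera adjusted p = 0.000513; adjusted p = 0.546 with an estimated correlation). Of these 2 passed adjusted over the list alone, mt-Nd6, at 457 ± 129 against 968 ± 84.3 RPKM, and mt-Nd3. This list was 0.67 in wildtype replicate 3 and -0.32 and -0.33 in the other wildtype libraries, and its call ended without wildtype replicate 3 (median -0.19, camera adjusted p = 0.0552) or under quantile normalization (median -0.18, 0.107). Gene length moved with the groups as well. The median log2 fold change of protein-coding genes was -0.15 in the shortest 20% and 0.23 in the longest 20%. With the length and GC trend removed, 12 lists were called; the mitochondrial (median -0.25, camera adjusted p = 0.144), histone (-0.22, 0.0756) and spongiotrophoblast (-0.16, 0.303) lists no longer were. The smooth muscle list kept a median of 0.35 and lay at the threshold (0.0501).

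**Figure D3:**
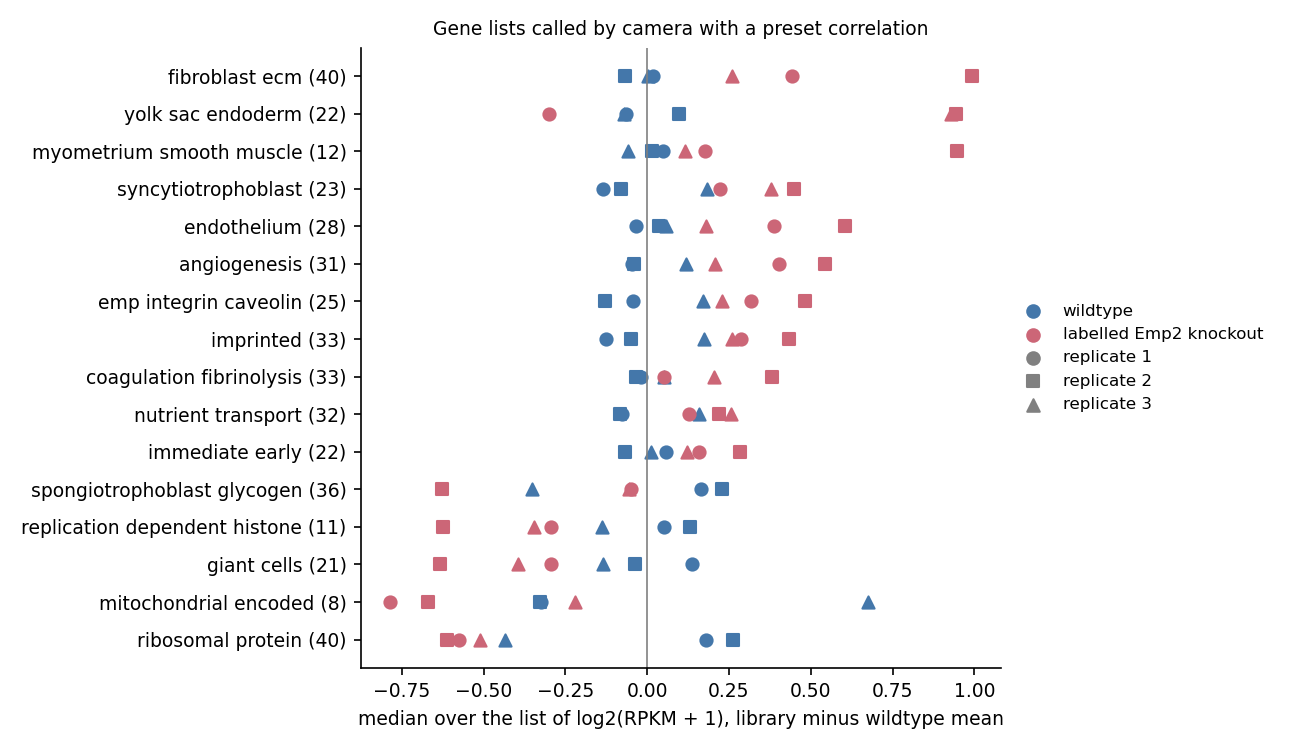
Median over each list of log2(RPKM + 1), each library minus the wildtype mean, for the 16 lists called by camera with a preset correlation (measured genes in brackets), with wildtype in blue and libraries labelled Emp2 knockout in red. Ribosomal protein genes lay at -0.43 in wildtype replicate 3, near the knockout libraries, and yolk sac endoderm genes at -0.30 in knockout replicate 1.

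The remaining lists were not called by camera with a preset correlation. Of 39 hypoxia genes, 27 had higher means, with a median of 0.08 (camera adjusted p = 0.505), and Bnip3, a mitophagy receptor, stood at 50.8 ± 1.13 against 79.5 ± 21.8 RPKM. The maternal decidua list had 18 of 25 genes with higher means and a median of 0.24 (0.141), though Prl3c1 stood at 34.3 ± 5.09 against 63.0 ± 20.1 RPKM. The uterine natural killer list (10 genes, 0.983) had a median of -0.05, a mean of 0.01 and a lower direction by camera, with 1 member past the threshold adjusted over the list alone, Itga2. The macrophage list (20 genes, median -0.04, 0.658) also had 1, Lyve1. The erythroid list (15 genes, 0.983) had a positive median, 0.05, and mean, 0.10, while camera gave it a lower direction; Tfrc, the transferrin receptor, ranged from 16.9 to 107 RPKM within wildtype and averaged 129 ± 36.1 RPKM in the knockout libraries. The uterine epithelium (10 genes, median 0.04, 0.983) had Muc1 at 55.0 ± 7.81 against 39.9 ± 8.11 RPKM. The interferon list (28 genes, median -0.01, 0.242) had Ifi27l2a at 9.07 ± 1.63 against 19.5 ± 8.08 RPKM. Dividing-cell genes (24 genes, median 0.24, 0.0932) had Mcm4, a replication helicase subunit, at 5.16 ± 0.814 against 3.83 ± 0.151 RPKM. Their median ranged from 0.04 to 0.38 with 1 library left out. The unfolded protein and amino acid stress list (26 genes, median -0.02, 0.383) had Ddit3 at 21.3 ± 1.75 against 28.5 ± 2.65 RPKM. With 4 measured members, the neutrophil list was not tested; all 4 had lower means, and S100a8 stood at 102 ± 9.76 against 221 ± 82.7 RPKM and passed adjusted over the list alone.

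Genes beside Emp2 were compared because a region carried along with a targeted allele could differ between the groups. The fixed list of 29 neighbours had a median of 0.09 (camera adjusted p = 0.658), with Ubn1 at 23.2 ± 0.463 against 18.4 ± 2.16 RPKM. Of 36 tested genes within 5 Mb of Emp2 on chromosome 16, 0 passed the threshold, against 2 of 12927 elsewhere (two-sided Fisher's exact p = 1). At an unadjusted p under 0.05 there were 8 of the 36, 22.2%, against 16.6% of the rest (two-sided Fisher's exact p = 0.370).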

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

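Settings chosen after seeing the data were the 10-read filter, removal of short solved lengths, the Y-linked term, the libraries with Y-linked RNA alone, the length and GC trend (with and without wildtype replicate 3), quantile normalization and robust variances; the cause of a change was not tested unless given. The 2 genes called (1 higher, 1 lower) were 0 and 0 under limma-voom, a mean of 1 CPM, a mean of 10 reads, or without lengths of 20 bases or less, with 0 at 2-fold; the filters remove these 1-to-2-read genes by construction. A pseudocount of 0.1 or no filter gave 3 genes, 2 lower, with 3 and 2 changed 2-fold. The term for Y-linked RNA gave 1 gene (0 lower, 1 at 2-fold), and the 4 libraries with Y-linked RNA gave 5 (5 higher, 0 lower, 5 at 2-fold), and both settings compare knockout replicate 1 alone with wildtype, that library being assumed to vary like the others. At an unadjusted p under 0.05 they left 578 genes (141 higher, 437 lower) and 407 (121 higher, 286 lower). Leaving out each library gave from 3 to 3374 genes, 1 to 2148 higher, 1 to 1226 lower and 3 to 221 at 2-fold, the highest each time without wildtype replicate 3. With the length and GC trend also removed, leaving it out gave 980 genes (228 higher, 752 lower, 122 at 2-fold). Median-ratio scaling moved the median gene from 0.06 to -0.01. Emp2 stayed lower and short of the threshold under every setting run (-0.47 to -0.08).

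Of the lists, 16 called became 0 with an estimated correlation and 0 by fry for one direction (its test for either direction called the macrophage and endothelial lists, adjusted p = 8.94e-05 and 0.0406), and 11 to 17 with a library left out. On ranks, where the preset correlation was kept, camera called the same 16 lists, with the largest adjusted p for smooth muscle (0.0267). Camera with a preset correlation called 12 with the Y-linked term, 14 in its libraries, 12 with the trend removed, 11 with it removed and wildtype replicate 3 left out, and 13 under quantile normalization. Both Y-linked settings ended the coagulation, smooth muscle, spongiotrophoblast and giant cell calls and called yolk sac lower (adjusted p = 0.000386 and 0.00270). With the trend removed and wildtype replicate 3 left out, the spongiotrophoblast (median -0.27, camera adjusted p = 0.0604), giant cell (-0.26, 0.119), smooth muscle (0.23, 0.317), mitochondrial (0.14, 0.759) and histone (-0.19, 0.246) calls ended. The spongiotrophoblast median was then no smaller in size than the -0.23 with all libraries. Medians that changed sign were erythroid (-0.0275) and uterine epithelium (-0.0347) under median-ratio scaling; uterine natural killer (0.24), yolk sac (-0.30), uterine epithelium (-0.0927) and stress (0.103) with the Y-linked term or its libraries; uterine natural killer (0.13), macrophage (0.0566) and stress (0.00474) with the trend removed; hypoxia (-0.0364), erythroid (-0.103), macrophage (0.0298), interferon (0.00185) and mitochondrial (0.145) with it removed and wildtype replicate 3 left out; spongiotrophoblast (0.0640) and stress (0.0110) under quantile normalization; and spongiotrophoblast (0.0863) without multigene families. With 1 library left out, medians ranged from -0.23 to 0.29 (erythroid), -0.0625 to 0.0132 (interferon), -0.13 to 0.0577 (macrophage), -0.11 to 0.0384 (stress), -0.0230 to 0.11 (uterine epithelium) and -0.28 to 0.36 (uterine natural killer). Camera with a preset correlation also called lists that it had not called with all libraries: uterine natural killer without knockout replicate 3 (adjusted p = 0.00699) and in the libraries with Y-linked RNA (0.00414); decidua with no filter (0.0416), without wildtype replicate 1 (0.0250) and without multigene families (0.0228); and dividing cells with no filter (0.0166), a replicate block (0.04997), without wildtype replicate 2 (0.0260), without knockout replicate 3 (0.000167) and in the libraries with Y-linked RNA (0.0442). A list counted as reversed when its median changed sign, or, where the alternative itself called the list, by the direction of that call. That rule replaced one on the direction camera gave, after the first rule had been seen to reverse many uncalled lists near 0, so it lists fewer reversals than the first rule did. The share of genes near Emp2 at an unadjusted p under 0.05, 22.2%, fell below that of the rest with the trend removed (13.9%), the Y-linked term (2.78%) and its libraries (0%), and ranged from 2.78% to 41.7% with a library left out.

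With a replicate block, 2 genes and 17 lists were called and the share near Emp2 was 8.33%, below the rest. Deviations of same-numbered libraries correlated at 0.031, 0.0032 and 0.013, and 0 of the 3 pairs passed 0.1. Differently numbered libraries gave from -0.061 to 0.050, so no pair of either kind passed that bound. The values give no sign that the numbers pair the samples, but cannot exclude a shared litter or batch. DESeq2 and the edgeR quasi-likelihood variants, planned for deposited counts, were not run; limma-voom was the only test run on the solved reads. Library size alone is the scaling of the values as deposited. Depth limits genes of few reads, the 2 called genes among them.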

Other observations

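The tests of a wrong label, of the Emp2 allele and of ribosomal protein pseudogenes were chosen after the result was seen, as was the fit with the length and GC trend removed and wildtype replicate 3 left out. The bounds for the length and GC tests were set before their values were seen, but after short genes had been seen to be lower and long genes higher. Without wildtype replicate 3, which lay near the knockout libraries on the first component and apart from both groups on the second, limma-trend called 2148 genes higher and 1226 lower of 12963. Dropping a library picked for its distance from its own group favours more calls by construction, so the list counts describe the other 5 placentas and do not add to the evidence for a genotype effect. With the length and GC trend also removed, 228 genes passed higher and 752 lower, so most of the higher calls ended. The list counts here are from the fit without that removal. There, 36 of 40 ribosomal protein genes passed lower over all genes tested. Higher were 13 of 25 genes of the EMP, integrin and caveolin list, 13 of 33 imprinted genes, 11 of 23 syncytiotrophoblast genes, 10 of 31 angiogenesis genes, 10 of 28 endothelial markers (1 lower) and 9 of 32 nutrient transporters (1 lower). Of 36 spongiotrophoblast and glycogen cell genes, 6 passed lower and 1 higher, and of 11 histone genes, a sign of library make-up, 4 passed lower. Further lists had 6 of 29 genes near Emp2 higher, 6 of 40 matrix genes higher, 1 of 22 yolk sac genes higher, 3 lower and 1 higher of 21 giant cell genes, and 4 higher and 3 lower of 39 hypoxia genes. Over all 12963 genes, 2148 passed higher and 1226 lower, so some of these counts are not above the common share. Those of the matrix, yolk sac and hypoxia lists lie below it. With all 6 libraries, 0 members of these lists passed.

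Wildtype replicate 3 differed from wildtype replicates 1 and 2 in more than its place on the components. Against their mean, its spongiotrophoblast and glycogen list lay at -0.53, its erythroid list at -0.53, its ribosomal protein list at -0.65, its uterine natural killer list at -0.46, its histone list at -0.21 and its stress list at -0.13, all below the 95% range of random lists matched on mean level. Its mitochondrially encoded list lay at 1.01 and its imprinted list at 0.26, above it. Members of a random list need not move together, so the range is too narrow for correlated lists. The estimated correlation was 0.78 within the ribosomal protein list and 0.82 within the mitochondrial list. The stress and imprinted lists lay just past their bounds, -0.123 and 0.255. Haemoglobin Hbb-b1 stood at 4743 RPKM in wildtype replicate 3, against 19553 and 26507 in the other wildtype libraries. Its 10 genes with most reads took 8.46% of the library, against 13.6% and 13.7%.

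A candidate explanation for that distance is a larger share of maternal decidua. The decidua list's median difference lay at the 44.0th percentile of random lists. That meets the bound written beforehand against this explanation, the 50th percentile or lower. The bound was moved to the 2.5th percentile after the value was seen, because the median, 0.10, lay well inside the range of random lists (-0.07 to 0.29) and so passed the first bound by less than its spread; under the first bound alone, the test would count against decidua. The lower uterine natural killer list, of 10 maternal cell markers, also points away from more maternal tissue, though it was not the test set for this. Xist reads, which maternal cells can add to, were higher in this library, 3727 against 1155 and 2011 in wildtype replicates 1 and 2. Its Y-linked reads were higher too, 3630 against 1983 and 2769. Read alone, the Xist reads would go with more maternal tissue, so these markers leave the question open. Gene length and GC content gave an R squared of 0.290 across protein-coding genes, short of the 0.5 set for the main cause. Leaving out this library gave 980 calls with the trend removed, against 3374 without that removal. Since dropping this library favours more calls by construction, the 980 do not show a distance beyond the trend. A trend may account for part of the distance. A wrong label could also place it there, but Emp2, 8.19 RPKM in this library, lay where the groups overlap and cannot decide. Differences between placentas of one genotype stay open, untested.

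The lower ribosomal protein genes and higher matrix genes of the libraries labelled knockout were weighed against length and GC bias. The ribosomal median kept 94.2% of its size after the trend was removed (-0.56 to -0.53, interquartile ranges 0.289 and 0.323). That argues against a trend on solved length and GC as the whole cause, but does not test a bias by transcript length. The list's median solved length was 1916 bases. Genes in the fifth of lengths around 2286.5 bases had a median log2 fold change of 0.01, so the trend left little to remove there. The matrix median kept 74.2% (0.64 to 0.48, interquartile ranges 0.341 and 0.302), just under the 75% set beforehand, so a part of it may follow length. Reads moving from ribosomal protein genes to their pseudogenes would raise the pseudogenes, but 62 of 63 were lower, with a median of -0.62 and an upper quartile of -0.47. That counts against such a move only. Reads shared with near-identical copies in a way that lets genes and pseudogenes fall together were not tested. RNA quality, a bias by transcript length, other sharing of reads with pseudogenes, tissue make-up, sex and genotype remain open.

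Emp2 RNA in the libraries labelled knockout averaged 85.6% of the wildtype mean. A knockout allele that leaves most of the transcript could give this, as could wrong labels, the highest knockout library standing at 8.70 RPKM, inside the wildtype range. Values for the whole gene cannot tell these apart, since neither reads by exon nor protein levels were analysed here.

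The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. For genes past the threshold, the real split gave 2 and the highest other split 4. At an unadjusted p under 0.05 the real split gave 2160 genes and the highest other split, which exchanged wildtype replicate 3 and knockout replicate 1, gave 2244. For lists called by camera with a preset correlation, the real split gave 16 and the highest other split 16.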
